A study of Mus musculus with 12 samples.

How the data were processed

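The samples were 12 RNA-seq libraries of total RNA from MC38 tumours, in 4 groups of 3: wild-type or TLR4-deleted hosts, with PBS or Salmonella intravenously, taken after 1 day. Groups were read from the genotype and treatment labels and replicate names from the titles. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 kit; no strand setting is given. Fastp, HISAT2 and HTSeq are named without versions or roles in the submitters' processing notes, and the genome build and annotation are not given in the sources used here.

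The authors deposited 1 table of values per library, and its unit was inferred from the values: they behave as FPKM, normalized by gene length and by library total. For 18608 of 18609 genes (99.99%) every library's FPKM was a whole number of fragments at 1 gene length, within 0.01 fragments, which gave 30512075 to 38764511 fragments per library and a median gene length of 3201 bp. Of the genes, 387 were at 0 in every library. The depth gives a value of 1 fragment in a 1 kb gene of 0.0258 to 0.0328 FPKM, and 3 fragments, the limit that a count of 0 allows, 0.0774 to 0.0983 FPKM; these cover counting error only.

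The design written before the data were examined assumed counts and a count test. That planned count test was not run on the recovered fragments either. Because the values were FPKM, the test was changed to limma 3.58.1 in R 4.3.3 on log2(FPKM / scaling factor + 0.5), with empirical Bayes moderation, an intensity trend and robust settings, on all 12 libraries with 1 mean per group and 8 residual degrees of freedom. Scaling factors were a trimmed mean of log ratios (30% of ratios and 5% of levels trimmed at each end, unweighted). Genes with at least 0.5 FPKM in at least 3 libraries were tested, and p-values are two-sided, adjusted by Benjamini-Hochberg over all tested genes, with 0.05 as threshold. Scaling factors were 0.844 and 0.845 for wild-type Salmonella F-1 and M-1 and 1.001 to 1.049 for the others. No library pair of a group held identical values; the chi-square per gene between mates was 19 to 196, far above sampling noise.

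The 5 comparisons were Salmonella against PBS in each host genotype, knockout against wild type under each treatment, and the interaction (knockout effect minus wild-type effect). The agreement of both treatment effects was a correlation across genes. Gene lists were fixed before the data were examined, 31 in all: 29 had at least 3 tested members, the list of mitochondrially encoded genes had 0 genes among those listed and the list of Y-linked genes and Xist had 2 tested members, Eif2s3y and Ddx3y, and was read only against the title letters. Lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison. With an estimated correlation no list passed in any comparison (0 higher and 0 lower in each). List calls thus hold only at the preset correlation, which may call too many. Some genes stand on more than 1 list: Lcn2, Il1b, Nos2, Ppbp, Vwf, Vegfa, Relb, Thy1, Lbp and Il18.

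Genes are named by a rule fixed beforehand: Tlr4, then the 6 largest rises and 6 largest falls per comparison among genes that passed, with a mean log2(FPKM + 0.5) above 1 (fixed for log2 CPM) and no overlap between groups, then 2 genes per list with the smallest p in wild-type hosts, and 2 per list called for the interaction. Predicted and RIKEN symbols were left out. Some genes that the rule names are not reported here. Positions and GC content were taken from GENCODE M21 (GRCm38), which may not be the authors' build. Genes with near-identical copies (Saa1, Ifit3b, H2 genes) are uncertain, since the authors' counting could split their fragments.

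The fit was tested on simulated data with 11776 genes, of which 200 were changed. For Salmonella against PBS in wild-type hosts it recovered 79% of genes changed by a fold of 2 and 95% at a fold of 4. Of 179 calls there, 5 were false. For the interaction it recovered 62% and 92%, with 5 false of 159 calls. The comparisons without changes gave 0 calls. The simulated noise was independent between genes and alike in all groups. The data had unequal spread between groups and 4312 calls in wild-type hosts, so these shares need not hold for them. Alternatives fixed beforehand were median-of-ratios scaling, no filter, only the groups compared, the replicate label or title letter in the model, each library left out, and the estimated correlation. Added after seeing the data were pseudocounts of 0.1 and 1, FPKM as deposited, voom on the recovered fragments, length and GC trends removed, and a minimum change of 1 on the log2 scale. The labels F and M of the titles are not explained in the labels.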

Results

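RNA was sequenced in 12 libraries from tumours of MC38, a mouse colon cancer line. The tumours grew in wild-type C57BL/6 hosts or in hosts with a TLR4 deletion (called knockout here). TLR4 is the receptor that senses the lipopolysaccharide of Gram-negative bacteria. Hosts received Salmonella or phosphate-buffered saline (PBS) intravenously, and tumours were taken after 1 day. Each of the 4 groups held 3 libraries, whose titles carry the labels F-1, M-1 and M-2. The labels do not say that the 3 libraries of a group came from separate animals. Libraries with letter F held 0 to 1 fragments of Y-linked genes and those with letter M 266 to 1247, so F-1 and the M libraries of a group did not come from 1 host. M-1 and M-2 lay further apart than F-1 and M-1 among wild-type Salmonella libraries (chi-square per gene 196 against 62.7) and knockout PBS libraries (74.2 against 35.1), so a repeat of 1 sample did not set their spread there. For the other groups M-1 and M-2 are not stated to be separate animals, so p-values measure the spread between these libraries, which may in part be technical. Libraries held 30512075 to 38764511 fragments on listed genes. In wild-type hosts they held 37118298 to 37832218 under PBS and 30512075 to 37823851 under Salmonella, and in knockout hosts 33107147 to 38424367 and 36999195 to 38764511. At this depth 1 fragment in a 1 kb gene equalled 0.0258 to 0.0328 FPKM (fragments scaled to gene length and library total). Of 18609 listed genes, 12164 were tested. Levels are mean FPKM ± SD of 3 libraries (n = 3), and fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes.

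Tlr4 itself, on chromosome 4 from 66827584 to 66930284 (GRCm38), was measured at 2.53 ± 0.053 FPKM under PBS and 2.99 ± 0.685 under Salmonella in wild-type hosts. In knockout hosts it was at 2.29 ± 0.792 and 1.83 ± 0.116 FPKM. The single knockout libraries lay between 1.59 and 3.15 FPKM and held 488 to 1019 fragments each, so Tlr4 RNA was present in every library with a knockout label. Under Salmonella, knockout hosts differed from wild-type hosts by log2 fold change -0.72, SE 0.21, adjusted p = 0.0502, which did not pass, and under PBS by log2 fold change -0.15, SE 0.21, adjusted p = 1.0. The tumour cells are not stated to lack Tlr4 and the deleted part of the gene is not stated, so total Tlr4 is a poor check of the labels.

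In wild-type hosts, genes of neutrophils and of the acute-phase response rose 1 day after Salmonella. S100a8 and S100a9, the subunits of calprotectin, rose from 5.29 ± 2.98 to 3954 ± 4465 FPKM (log2 fold change 9.11, SE 0.69, adjusted p = 0.000132) and from 3.64 ± 3.52 to 3733 ± 4259 FPKM (log2 fold change 9.71, SE 0.77, adjusted p = 0.000136). Lcn2, which binds bacterial siderophores, rose to 1180 ± 1002 FPKM (log2 fold change 9.64, SE 0.75, adjusted p = 0.000132), and the acute-phase gene Saa3 rose to 4514 ± 1324 FPKM from 25.3 ± 25.3 (log2 fold change 8.12, SE 0.82, adjusted p = 0.000438). Cd74, the MHC class II invariant chain, fell from 499 ± 239 to 78.8 ± 51.7 FPKM (log2 fold change -2.51, SE 0.69, adjusted p = 0.0203). The macrophage receptor Cx3cr1 fell from 7.24 ± 0.658 to 0.90 ± 1.47 FPKM (log2 fold change -2.92, SE 0.53, adjusted p = 0.00411).

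**Figure D1:**
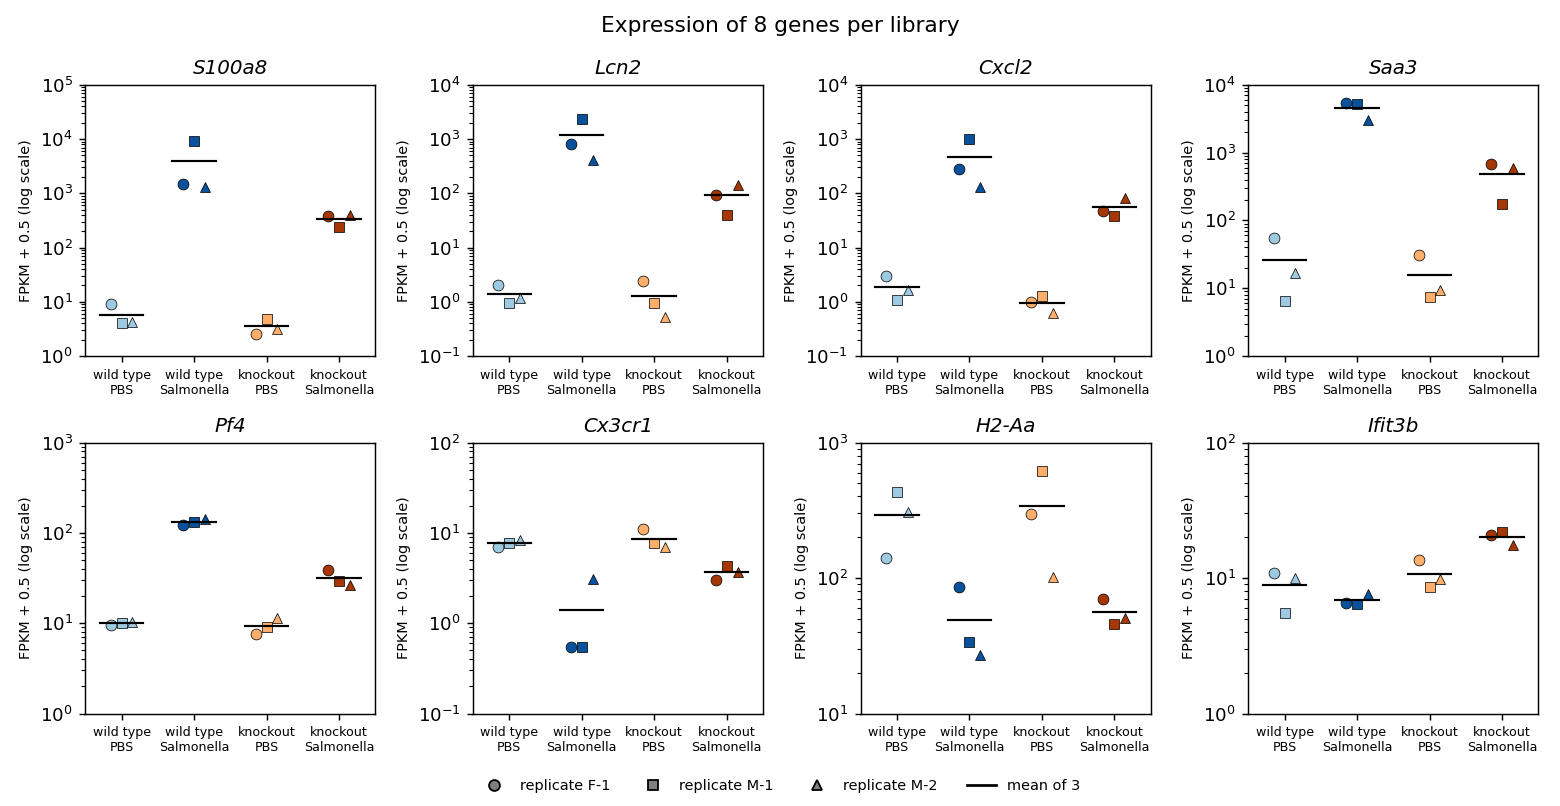
FPKM + 0.5 on a log axis for 8 genes in each of the 12 libraries, by group, with symbols for the replicate label and a bar for the mean of 3. S100a8, Lcn2, Cxcl2, Saa3 and Pf4 were higher under Salmonella in every library of both host genotypes; for Ifit3b the knockout Salmonella libraries lay above the wild-type Salmonella libraries.

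Of the neutrophil markers, 22 of 22 tested members rose (22 rose adjusted over the list alone), median 4.41. The neutrophil list had adjusted p = 5.16e-18, and adjusted p = 0.417 with an estimated correlation. Retnlg, a resistin-like gene of neutrophils, reached 248 ± 209 FPKM (8.30, adjusted p = 8.36e-05) and the chemokine receptor Cxcr2 17 ± 8.26 FPKM (5.03, adjusted p = 8.73e-05). Of the neutrophil and monocyte chemokines, 12 of 15 tested members rose (13 rose adjusted over the list alone), median 3.07. The chemokine list had adjusted p = 2.08e-09, and adjusted p = 0.417 with an estimated correlation. Cxcl3 rose to 293 ± 287 FPKM (8.42, adjusted p = 0.000132; not passed in voom), Cxcl5 to 70.2 ± 35.2 (6.09, adjusted p = 0.000132) and Cxcl2 to 475 ± 466 (7.78, adjusted p = 0.000206). Of the inflammatory cytokines, 9 of 18 tested members rose and 1 fell (10 rose and 1 fell adjusted over the list alone, and 5 passed in voom), median 1.26. The cytokine list had adjusted p = 0.00217, and adjusted p = 0.584 with an estimated correlation. Il1b rose from 9.9 ± 0.67 to 380.4 ± 334 FPKM (5.0, adjusted p = 0.000937). Of the NF-kB target and feedback genes, 19 of 24 tested members rose (21 rose adjusted over the list alone), median 1.29. The NF-kB list had adjusted p = 2.08e-09, and adjusted p = 0.544 with an estimated correlation. Among them were Sod2, the mitochondrial superoxide dismutase (2.23, adjusted p = 0.000937), and Zc3h12a, an RNase that degrades cytokine transcripts (2.32, adjusted p = 0.00111). Of the acute-phase, complement and antimicrobial genes, 17 of 20 tested members rose (17 rose adjusted over the list alone), median 2.70. The acute-phase list had adjusted p = 2.08e-09, and adjusted p = 0.46 with an estimated correlation. Saa1 rose to 33.7 ± 16.6 FPKM (5.99, adjusted p = 0.000132); it has near-identical copies, so its fragments are uncertain. Of the TLR4 pathway and bacterial sensing genes, 7 of 23 tested members rose and 2 fell (7 rose and 2 fell adjusted over the list alone), median 0.18. The TLR4 pathway list had adjusted p = 0.188. Cd14, the lipopolysaccharide co-receptor, rose from 11.3 ± 2.38 to 333 ± 222 FPKM (4.74, adjusted p = 0.00086). Of the inflammasome and pyroptosis genes, 6 of 17 tested members rose and 1 fell (6 rose and 1 fell adjusted over the list alone), median 0.24 (0.08 with FPKM as deposited). The inflammasome list had adjusted p = 0.00838, and adjusted p = 0.596 with an estimated correlation. Nlrp3 rose (2.53, adjusted p = 0.00274). Of the immediate early and stress genes, 8 of 18 tested members rose and 1 fell (11 rose and 2 fell adjusted over the list alone), median 0.54 (0.34 with FPKM as deposited). The immediate early list had adjusted p = 0.0101, and adjusted p = 0.656 with an estimated correlation. The heme oxygenase gene Hmox1 rose to 909.6 ± 246 FPKM (2.17, adjusted p = 0.000445).

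Markers of vessels and blood rose beside the neutrophil genes. Of the endothelial cell markers, 18 of 20 tested members rose (18 rose adjusted over the list alone), median 1.23. The endothelial list had adjusted p = 5.78e-10, and adjusted p = 0.46 with an estimated correlation. The endothelial transcription factor Sox18 went from 3.15 ± 0.508 to 10.4 ± 0.94 FPKM (1.78, adjusted p = 0.000148). Of the erythroid and platelet markers, 7 of 8 tested members rose (8 rose adjusted over the list alone), median 2.57. The erythroid and platelet list had adjusted p = 2.78e-05, and adjusted p = 0.46 with an estimated correlation. Pf4, platelet factor 4, rose from 9.46 ± 0.381 to 132 ± 10.1 FPKM (log2 fold change 3.93, SE 0.16, adjusted p = 2.07e-07). Of the coagulation and fibrinolysis genes, 12 of 15 tested members rose and 1 fell (12 rose and 1 fell adjusted over the list alone), median 1.55. The coagulation list had adjusted p = 3.18e-05, and adjusted p = 0.576 with an estimated correlation. Thbs1, thrombospondin 1, rose to 211 ± 159 FPKM (3.72, adjusted p = 0.00145). Of the angiogenesis and vascular growth genes, 7 of 17 tested members rose and 4 fell (7 rose and 4 fell adjusted over the list alone), median 0.31. The angiogenesis list had adjusted p = 0.522; Angptl4 rose (2.56, adjusted p = 0.000445) and Apln, apelin, fell (-1.01, adjusted p = 0.000942). Of the skeletal muscle markers, 9 of 12 tested members rose (12 rose adjusted over the list alone, and 5 passed in voom), median 2.44. The muscle list had adjusted p = 3.18e-05, and adjusted p = 0.544 with an estimated correlation. Mylpf, a myosin light chain gene, rose to 14.2 ± 5.52 FPKM (2.96, adjusted p = 0.00443). The mean level of the muscle list against wild-type PBS was 2.82, 2.66 and 1.78 in the wild-type Salmonella libraries F-1, M-1 and M-2. Of the fibroblast and pericyte markers, 8 of 21 tested members rose and 3 fell (10 rose and 3 fell adjusted over the list alone), median 0.65. The fibroblast list had adjusted p = 0.0632. Dcn, decorin, rose to 279 ± 66 FPKM (1.28, adjusted p = 0.00338). Of the oxidative phosphorylation genes, 13 of 25 tested members rose (16 rose adjusted over the list alone), median 0.36 (0.15 with FPKM as deposited). The oxidative phosphorylation list had adjusted p = 7.42e-05, and adjusted p = 0.656 with an estimated correlation. Ndufa4, a respiratory chain gene, rose (0.75, adjusted p = 0.00825).

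Of the MHC class II presentation genes, 1 of 12 tested members rose and 7 fell (1 rose and 7 fell adjusted over the list alone), median -0.90. The MHC class II list had adjusted p = 0.0221, and adjusted p = 0.656 with an estimated correlation. H2-Aa fell from 293 ± 146 to 48.2 ± 32.2 FPKM (-2.43, adjusted p = 0.021), while the member that rose was the costimulatory ligand Cd80 (2.36, adjusted p = 0.00557). The MHC class II list lost its call without wild-type PBS M-1 (adjusted p = 0.0521) and wild-type Salmonella M-2 (adjusted p = 0.196). Of the interferon-gamma-induced genes, 1 of 31 tested members rose and 4 fell (1 rose and 3 fell adjusted over the list alone, and 3 passed in voom), median -0.51. The interferon-gamma list had adjusted p = 0.0433, and adjusted p = 0.805 with an estimated correlation. Irgm2, an interferon-inducible GTPase, fell (-1.18, adjusted p = 0.00713) and Nos2, inducible nitric oxide synthase, rose to 105 ± 47.9 FPKM (3.11, adjusted p = 0.00312). The interferon-gamma list lost its call without wild-type PBS F-1 (adjusted p = 0.0576), wild-type PBS M-2 (adjusted p = 0.0545) and wild-type Salmonella M-2 (adjusted p = 0.616). With FPKM as deposited, the MHC class II and interferon-gamma lists were no longer called. Of the hypoxia and glycolysis genes, 1 of 25 tested members rose and 10 fell (1 rose and 11 fell adjusted over the list alone), median -0.24 (-0.44 with FPKM as deposited). The hypoxia list had adjusted p = 0.00605, and adjusted p = 0.656 with an estimated correlation. The kinase genes Pdk1 (-0.74, adjusted p = 0.000937) and Hk1 (-0.61, adjusted p = 0.000987) fell. This hypoxia list call ended without wild-type Salmonella M-2 (adjusted p = 0.209).

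The other lists did not pass in wild-type hosts. Of the type I interferon-stimulated genes, 3 of 34 tested members rose and 2 fell (2 rose and 1 fell adjusted over the list alone), median 0.022. The type I interferon list had adjusted p = 0.666. Slfn4 rose (3.34, adjusted p = 0.00417). Of the MHC class I presentation genes, 1 of 21 tested members rose and 3 fell (0 adjusted over the list alone), median 0.084 but mean -0.006. The MHC class I list had adjusted p = 0.807; the test pointed down. Of the T and NK cell markers, 1 of 23 tested members rose and 2 fell (0 adjusted over the list alone, and 0 passed in voom), median -0.26. The T and NK cell list had adjusted p = 0.268. Cd8a fell (-1.44, adjusted p = 0.0384; not passed in voom). Of the cytotoxic lymphocyte effector genes, 2 of 15 tested members rose and 1 fell (2 rose and 1 fell adjusted over the list alone), median -0.57. The cytotoxic list had adjusted p = 0.454. The proteoglycan gene Srgn rose (3.17, adjusted p = 0.00266). Of the B cell markers, 0 of 4 tested members passed in limma and 0 in voom, with 1 at an unadjusted p under 0.05 (0 adjusted over the list alone), median -0.16. The B cell list had adjusted p = 0.454. Of the macrophage and monocyte markers, 8 of 25 tested members rose and 4 fell (8 rose and 5 fell adjusted over the list alone), median -0.20 but mean 0.40. The macrophage list had adjusted p = 0.905; the test pointed up. Chil3 rose (4.41, adjusted p = 0.00186) and the monocyte chemokine receptor Ccr2 fell (-1.55, adjusted p = 0.00329). Of the dendritic cell markers, 2 of 9 tested members rose and 1 fell (2 rose and 1 fell adjusted over the list alone), median 0.17. The dendritic cell list had adjusted p = 0.971; the test pointed down. The integrin gene Itgax fell (-2.25, adjusted p = 0.000136). With FPKM as deposited the medians of the type I interferon, MHC class I, dendritic cell and TLR4 pathway lists changed sign, to -0.18, -0.118, -0.013 and -0.023.

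Markers of other tissue components gave small sets. Of the tumour epithelial markers, 2 of 4 tested members rose (2 rose adjusted over the list alone), median 0.56. The epithelial list had adjusted p = 0.0803. Of the adipocyte markers, 0 of 4 tested members passed in limma and 0 in voom, with 0 at an unadjusted p under 0.05 (0 adjusted over the list alone), median 0.70. The adipocyte list had adjusted p = 0.673. Of the keratinocyte and skin markers, 0 of 4 tested members passed in limma and 0 in voom, with 1 at an unadjusted p under 0.05 (0 adjusted over the list alone), median 0.47. The keratinocyte list had adjusted p = 0.563. Of the cell cycle genes, 1 of 30 tested members rose and 6 fell (3 fell adjusted over the list alone), median -0.14. The cell cycle list had adjusted p = 0.0917. Foxm1, a mitotic transcription factor, fell (-0.71, adjusted p = 0.00238).

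In all, 4312 genes passed at an adjusted p under 0.05 in wild-type hosts, 2337 higher and 1975 lower (54.2% higher), and 5781 had an unadjusted p under 0.05. With FPKM as deposited, where the median of all genes shifted by -0.186, 30.8% of the calls were higher. Of the calls, 876 changed by at least 1 on the log2 scale (712 higher, 164 lower). No overlap between groups was seen for 3999 of the calls, which choosing genes by p favours. Of all genes 45.4% had none, against 10% expected by chance. The count was 2997 without wild-type PBS F-1, 2759 without PBS M-1 and 2371 without PBS M-2. It was 2157 without Salmonella F-1, 2400 without Salmonella M-1 and 6290 without Salmonella M-2. Of the 85 genes named by rule that passed, 15 lost the call without at least 1 library: 7 without PBS F-1, 10 without PBS M-1, 14 without PBS M-2, 10 without Salmonella F-1, 12 without Salmonella M-1 and 4 without Salmonella M-2. The 15 included Cd74, H2-Aa and Cd8a. Of the 85, 80 passed in voom.

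**Figure D2:**
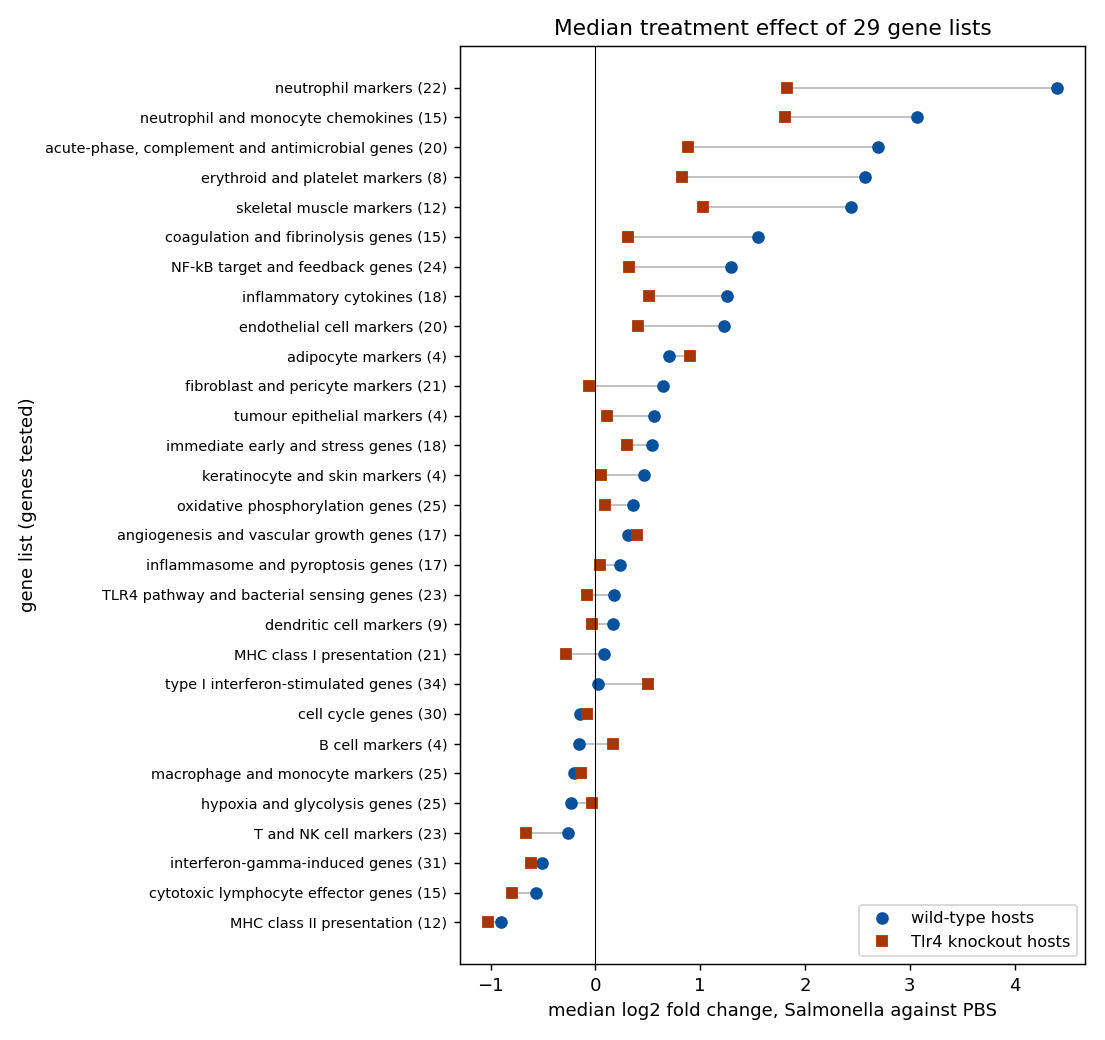
Median log2 fold change, Salmonella against PBS, of 29 gene lists (vertical axis, genes tested in brackets) in wild-type hosts (circles) and knockout hosts (squares). The neutrophil list had the highest median in both, at 4.41 and 1.82.

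In knockout hosts some neutrophil, chemokine and acute-phase genes passed in limma, but few of these calls held in voom; the test of the difference between hosts is the interaction. S100a8 went from 3.02 ± 1.16 to 337 ± 85.7 FPKM (log2 fold change 6.61, SE 0.69, adjusted p = 0.00591) and S100a9 from 0.647 ± 0.34 to 388 ± 127 FPKM (log2 fold change 8.39, SE 0.77, adjusted p = 0.00354). Lcn2 rose to 91.8 ± 52.1 FPKM (log2 fold change 6.23, SE 0.75, adjusted p = 0.00976), and the chemokines Cxcl2 and Cxcl3 to 55.7 ± 23 and 21.7 ± 3.53 FPKM. The largest falls among the named genes were of Cx3cl1, the ligand of Cx3cr1 (log2 fold change -1.44, SE 0.26, adjusted p = 0.0406), Itgax (log2 fold change -1.41, SE 0.21, adjusted p = 0.0157) and Ecrg4 (log2 fold change -1.32, SE 0.22, adjusted p = 0.0276). Platelet factor 4, Pf4, rose from 8.88 ± 1.97 to 31.2 ± 6.58 FPKM (log2 fold change 1.78, SE 0.16, adjusted p = 0.00167). In voom Pf4 and Itgax passed, while S100a8, S100a9, Lcn2, Cxcl2, Cxcl3, Cx3cl1 and Ecrg4 did not.

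Of the neutrophil markers, 9 of 22 tested members rose (14 rose adjusted over the list alone, and 1 passed in voom), median 1.82. The neutrophil list had adjusted p = 1.24e-17, and adjusted p = 0.436 with an estimated correlation. Of the chemokines, 4 of 15 tested members rose (10 rose adjusted over the list alone, and 0 passed in voom), median 1.80. The chemokine list had adjusted p = 4.25e-11, and adjusted p = 0.273 with an estimated correlation. Of the inflammatory cytokines, 1 of 18 tested members rose (4 rose and 1 fell adjusted over the list alone, and 0 passed in voom), median 0.51. The cytokine list had adjusted p = 0.0033, and adjusted p = 0.607 with an estimated correlation. The cytokine call ended without knockout PBS M-2 (adjusted p = 0.0734). Of the NF-kB target and feedback genes, 0 of 24 tested members passed in limma and 0 in voom, with 7 at an unadjusted p under 0.05 (0 adjusted over the list alone), median 0.32. The NF-kB list had adjusted p = 0.000307, and adjusted p = 0.607 with an estimated correlation. Of the acute-phase, complement and antimicrobial genes, 3 of 20 tested members rose (6 rose adjusted over the list alone, and 0 passed in voom), median 0.88. The acute-phase list had adjusted p = 5.76e-05, and adjusted p = 0.607 with an estimated correlation. Saa3 rose to 482 ± 267 FPKM (5.03, adjusted p = 0.0314), a call that ended in voom. Of the type I interferon-stimulated genes, 2 of 34 tested members rose (13 rose and 1 fell adjusted over the list alone, and 1 passed in voom), median 0.50. The type I interferon list had adjusted p = 6.69e-11, and adjusted p = 0.607 with an estimated correlation. Ifit1bl1 rose (1.34, adjusted p = 0.0177). Of the endothelial cell markers, 0 of 20 tested members passed in limma and 0 in voom, with 8 at an unadjusted p under 0.05 (5 rose adjusted over the list alone), median 0.40. The endothelial list had adjusted p = 2.65e-05, and adjusted p = 0.607 with an estimated correlation. Of the erythroid and platelet markers, 1 of 8 tested members rose (2 rose adjusted over the list alone), median 0.83. The erythroid and platelet list had adjusted p = 0.00146, and adjusted p = 0.607 with an estimated correlation.

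Of the coagulation and fibrinolysis genes, 0 of 15 tested members passed in limma and 0 in voom, with 5 at an unadjusted p under 0.05 (3 rose and 1 fell adjusted over the list alone), median 0.31. The coagulation list had adjusted p = 0.0408, and adjusted p = 0.732 with an estimated correlation. The coagulation call ended without knockout PBS F-1 (adjusted p = 0.0932), knockout PBS M-2 (adjusted p = 0.0592), knockout Salmonella F-1 (adjusted p = 0.0995) and knockout Salmonella M-2 (adjusted p = 0.0921). Of the immediate early and stress genes, 0 of 18 tested members passed in limma and 0 in voom, with 7 at an unadjusted p under 0.05 (1 rose adjusted over the list alone), median 0.30. The immediate early list had adjusted p = 0.0333, and adjusted p = 0.732 with an estimated correlation. The immediate early call ended without knockout PBS M-2 (adjusted p = 0.197), knockout Salmonella F-1 (adjusted p = 0.176) and knockout Salmonella M-2 (adjusted p = 0.0653). Of the skeletal muscle markers, 0 of 12 tested members passed in limma and 0 in voom, with 3 at an unadjusted p under 0.05 (0 adjusted over the list alone), median 1.02. The muscle list had adjusted p = 0.00256, and adjusted p = 0.607 with an estimated correlation. It rested on 1 library, since without knockout Salmonella F-1 (adjusted p = 0.184) the median was 0.16 and the call was lost. The mean level of the muscle list against wild-type PBS was 2.59 in knockout Salmonella F-1, -0.14 in M-1 and 0.67 in M-2.

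Lists of antigen presentation and of T, NK and cytotoxic cells had negative medians, while the B cell list did not pass (median 0.17). Of the MHC class II presentation genes, 0 of 12 tested members passed in limma and 0 in voom, with 7 at an unadjusted p under 0.05 (7 fell adjusted over the list alone), median -1.02. The MHC class II list had adjusted p = 4.42e-05, and adjusted p = 0.607 with an estimated correlation; H2-Aa was at 338 ± 261 FPKM under PBS and 55.3 ± 12.7 under Salmonella (-2.24, adjusted p = 0.129). Of the MHC class I presentation genes, 0 of 21 tested members passed in limma and 0 in voom, with 5 at an unadjusted p under 0.05 (0 adjusted over the list alone), median -0.28. The MHC class I list had adjusted p = 0.000794, and adjusted p = 0.607 with an estimated correlation. Of the interferon-gamma-induced genes, 0 of 31 tested members passed in limma and 0 in voom, with 8 at an unadjusted p under 0.05 (1 fell adjusted over the list alone), median -0.62. The interferon-gamma list had adjusted p = 4.42e-05, and adjusted p = 0.607 with an estimated correlation. The interferon-gamma call ended without knockout PBS M-1 (adjusted p = 0.053). Of the T and NK cell markers, 0 of 23 tested members passed in limma and 0 in voom, with 6 at an unadjusted p under 0.05 (3 fell adjusted over the list alone), median -0.66. The T and NK cell list had adjusted p = 4.42e-05, and adjusted p = 0.607 with an estimated correlation. Of the cytotoxic lymphocyte effector genes, 0 of 15 tested members passed in limma and 0 in voom, with 4 at an unadjusted p under 0.05 (0 adjusted over the list alone), median -0.80. The cytotoxic list had adjusted p = 0.00256, and adjusted p = 0.607 with an estimated correlation. The cytotoxic call ended without knockout PBS M-1 (adjusted p = 0.105). Of the cell cycle genes, 0 of 30 tested members passed in limma and 0 in voom, with 9 at an unadjusted p under 0.05 (3 fell adjusted over the list alone), median -0.083. The cell cycle list had adjusted p = 0.00391, and adjusted p = 0.607 with an estimated correlation. The cell cycle call ended without knockout Salmonella F-1 (adjusted p = 0.064). The other 12 lists did not pass.

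In knockout hosts 92 genes passed, 52 higher and 40 lower (56.5% higher), with 2330 at an unadjusted p under 0.05. With FPKM as deposited, 67.2% of the calls were higher, and of the 22 calls in voom 6 were higher and 16 lower. At least 1 on the log2 scale was reached by 28 of them (23 higher, 5 lower). All 92 had no overlap between groups, which choosing genes by p favours. Of all genes 29.4% had none, against 10% expected by chance. The count moved with every library: 5 without knockout PBS F-1, 7 without PBS M-1, 297 without PBS M-2, 4 without Salmonella F-1, 28 without Salmonella M-1 and 6 without Salmonella M-2. Of the 19 genes named by rule that passed, 15 lost the call without at least 1 library (14, 13, 0, 15, 6 and 15 in the same order); S100a8, S100a9, Retnlg and Pf4 were the other 4. Of the 19, 5 passed in voom, and Pf4 was the only one of those 4 to do so.

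**Figure D3:**
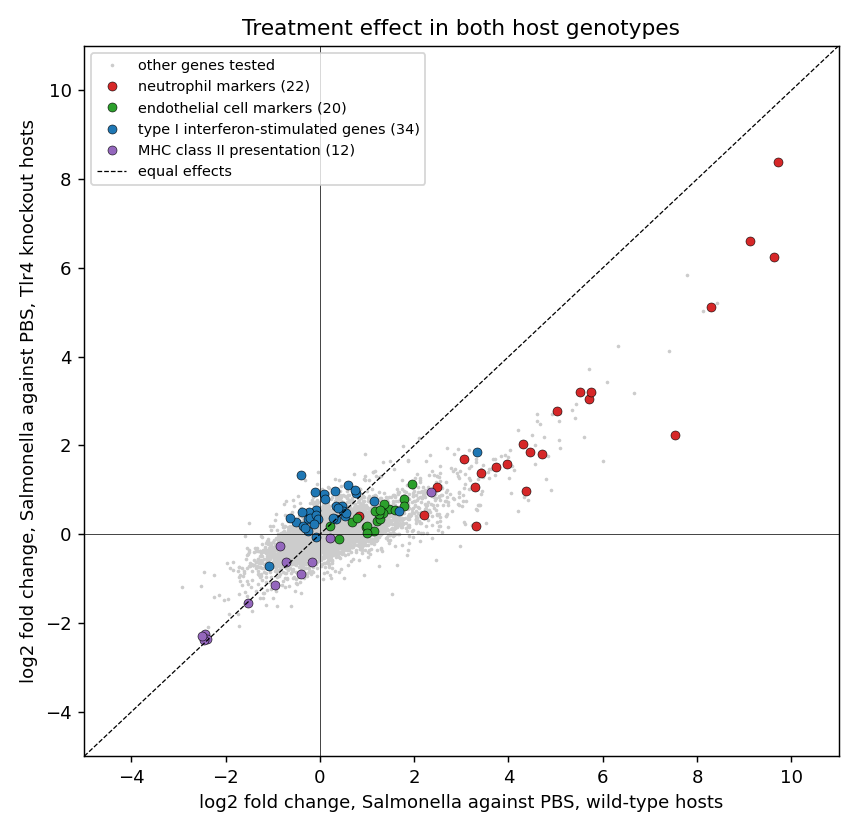
Fitted log2 fold change, Salmonella against PBS, in wild-type hosts (horizontal) and knockout hosts (vertical) for 12164 tested genes, with 4 lists in colour and a dashed line of equal effects. Most neutrophil and endothelial markers lie below the line on the positive side.

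Across genes, the treatment effects in wild-type and knockout hosts, which share no libraries, correlated with Pearson r = 0.767 and Spearman rho = 0.653; genes are not independent replicates, so no p is given. The sign was the same for 74.1% of genes. Of the genes called for the mean effect over both genotypes, the 2428 higher ones had medians of 0.59 in wild-type and 0.29 in knockout hosts, and 86.6% had the smaller effect in knockout hosts. The 2162 lower ones had medians of -0.49 and -0.27, and 83.3% were smaller in knockout hosts. Of the calls, 43 were higher in both genotypes, against 9.99 for independent lists, and 34 were lower in both, against 6.5; 0 passed in opposite directions.

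Under PBS, no gene passed between the tumours of knockout and wild-type hosts. Limma called 0 of 12164 genes, the smallest adjusted p was 1, 176 genes had an unadjusted p under 0.05, and voom on the recovered fragments also called 0. The neutrophil gene S100a8 was at 3.02 ± 1.16 FPKM in knockout and 5.29 ± 2.98 in wild-type hosts (log2 fold change -0.65, SE 0.69, adjusted p = 1.0), and the interferon-inducible Cmpk2 at 35.1 ± 6.3 and 28.9 ± 9.08 FPKM (log2 fold change 0.31, SE 0.23, adjusted p = 1.0). Of all genes 7.9% had no overlap between groups, against 10% by chance.

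Some lists had small shifts under PBS. Of the type I interferon-stimulated genes, 0 of 34 tested members passed in limma and 0 in voom, with 0 at an unadjusted p under 0.05 (0 adjusted over the list alone), median 0.18. The type I interferon list had adjusted p = 8.11e-06, and 0.907 with an estimated correlation. That interferon call ended without wild-type PBS M-1 (adjusted p = 0.819) and knockout PBS F-1 (adjusted p = 0.403). Of the interferon-gamma-induced genes, 0 of 31 tested members passed in limma and 0 in voom, with 0 at an unadjusted p under 0.05 (0 adjusted over the list alone), median 0.22. The interferon-gamma list had adjusted p = 0.0015, and 0.953 with an estimated correlation. Without knockout PBS F-1 the call ended (adjusted p = 0.11) and without knockout PBS M-1 the median was -0.18 (adjusted p = 0.116). Of the MHC class I presentation genes, 0 of 21 tested members passed in limma and 0 in voom, with 0 at an unadjusted p under 0.05 (0 adjusted over the list alone), median 0.14. The MHC class I list had adjusted p = 0.0011, and 0.953 with an estimated correlation. The class I call ended without wild-type PBS M-2 (adjusted p = 0.0531), knockout PBS F-1 (adjusted p = 0.0538) and knockout PBS M-1 (adjusted p = 0.635). Of the cytotoxic lymphocyte effector genes, 0 of 15 tested members passed in limma and 0 in voom, with 0 at an unadjusted p under 0.05 (0 adjusted over the list alone), median 0.37. The cytotoxic list had adjusted p = 0.00139, and 0.907 with an estimated correlation. Without wild-type PBS F-1 the call ended (adjusted p = 0.204) and without knockout PBS M-1 the median was -0.18 (adjusted p = 0.616). Of the cell cycle genes, 0 of 30 tested members passed in limma and 0 in voom, with 0 at an unadjusted p under 0.05 (0 adjusted over the list alone), median 0.10. The cell cycle list had adjusted p = 5.28e-06, and 0.661 with an estimated correlation. Of the hypoxia and glycolysis genes, 0 of 25 tested members passed in limma and 0 in voom, with 3 at an unadjusted p under 0.05 (0 adjusted over the list alone), median -0.16. The hypoxia list had adjusted p = 2.91e-09, and 0.661 with an estimated correlation.

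Of the erythroid and platelet markers, 0 of 8 tested members passed in limma and 0 in voom, with 3 at an unadjusted p under 0.05 (0 adjusted over the list alone), median -0.61. The erythroid and platelet list had adjusted p = 0.00019, and 0.661 with an estimated correlation. The erythroid and platelet call ended without knockout PBS M-1 (adjusted p = 0.095). Of the angiogenesis and vascular growth genes, 0 of 17 tested members passed in limma and 0 in voom, with 1 at an unadjusted p under 0.05 (0 adjusted over the list alone), median -0.19. The angiogenesis list had adjusted p = 0.0011, and 0.661 with an estimated correlation. The angiogenesis call ended without knockout PBS M-1 (adjusted p = 0.0693). Of the fibroblast and pericyte markers, 0 of 21 tested members passed in limma and 0 in voom, with 0 at an unadjusted p under 0.05 (0 adjusted over the list alone), median -0.17. The fibroblast list had adjusted p = 0.00471, and 0.907 with an estimated correlation. The fibroblast call ended without wild-type PBS F-1 (adjusted p = 0.262), wild-type PBS M-2 (adjusted p = 0.109), knockout PBS M-1 (adjusted p = 0.116) and knockout PBS M-2 (adjusted p = 0.15). The other 20 lists did not pass, though without knockout PBS M-2 the macrophage list was higher (median 0.30, adjusted p = 0.000473) and so was the acute-phase list (median 0.23, adjusted p = 0.0201).

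Under Salmonella, limma called part of the neutrophil (17 of 22), acute-phase (10 of 20), erythroid and platelet (7 of 8) and endothelial (15 of 20) genes lower in knockout than in wild-type hosts. Of the type I interferon-stimulated genes, 16 of 34 were called higher. No list passed in camera with an estimated correlation. Ngp, neutrophilic granule protein, was at 2.24 ± 1.81 FPKM in knockout against 134 ± 132 in wild-type hosts (log2 fold change -5.47, SE 0.68, adjusted p = 0.0081), and Saa1 at 1.56 ± 1.1 against 33.7 ± 16.6 (log2 fold change -4.27, SE 0.44, adjusted p = 0.00422). The B cell chemoattractant Cxcl13 was at 2.87 ± 2.57 against 31.3 ± 19.3 FPKM (log2 fold change -3.59, SE 0.62, adjusted p = 0.016). On the higher side, Ifit1bl1 was at 9.45 ± 0.97 against 2.64 ± 0.821 FPKM (log2 fold change 1.54, SE 0.20, adjusted p = 0.0081) and Cmpk2 at 48.9 ± 7.03 against 19.1 ± 5.52 (log2 fold change 1.19, SE 0.23, adjusted p = 0.0175). Xcl1, a chemokine that attracts cross-presenting dendritic cells, was at 3.87 ± 2.67 against 0.723 ± 0.745 FPKM (log2 fold change 1.79, SE 0.49, adjusted p = 0.0497). The calls on Ngp and Xcl1 ended in voom. With 1 library left out, the call on Xcl1 ended in 5 of 6 cases, all except wild-type Salmonella M-2 (adjusted p from 0.00835 to 0.164), and those on Cxcl13 and Cmpk2 in 4 of 6 (up to 0.0638 and 0.0792).

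**Figure D4:**
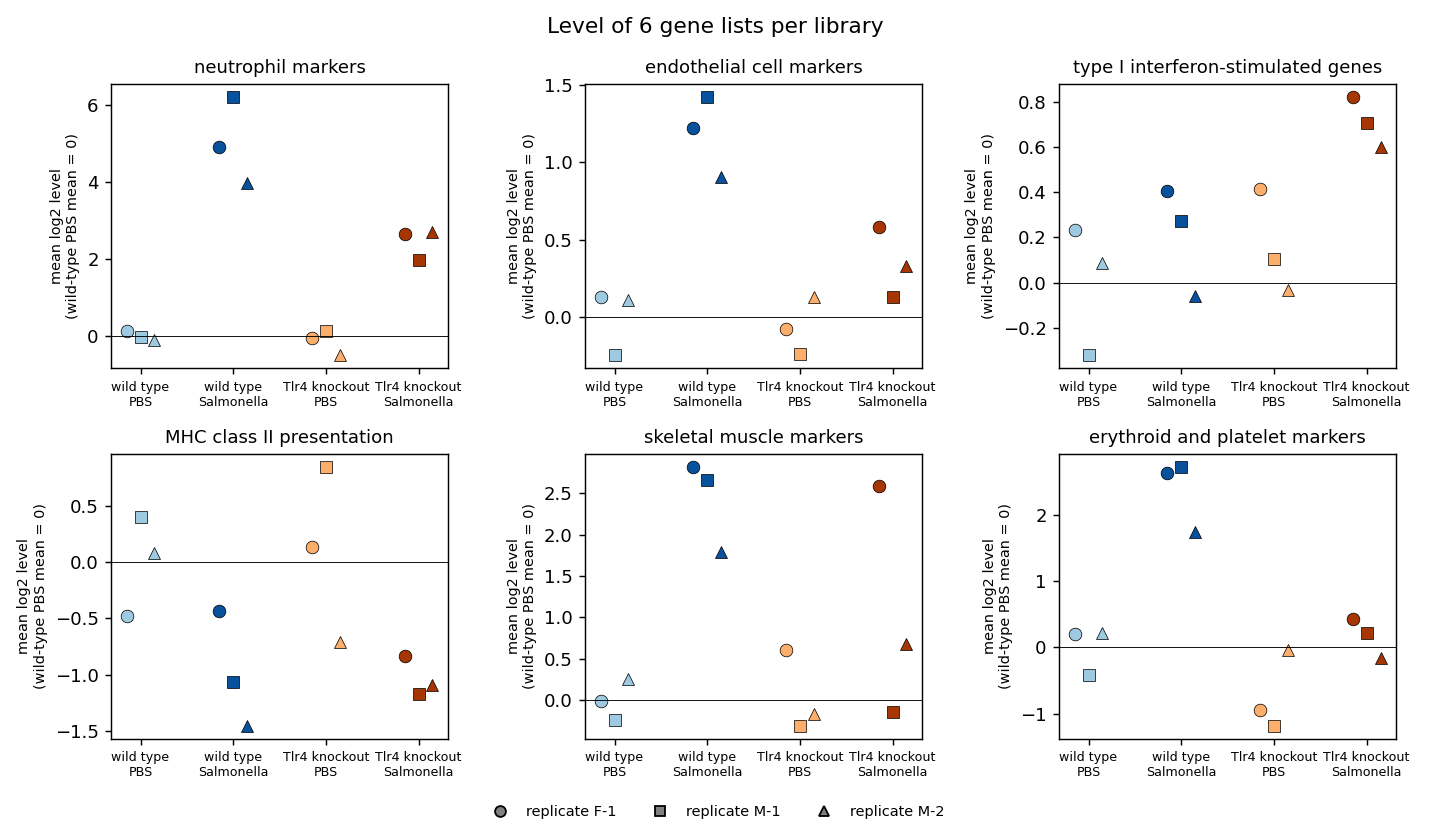
Mean log2 level of 6 gene lists in each library relative to the wild-type PBS mean, by group, with symbols for the replicate label. The neutrophil list was at 4.89, 6.21 and 3.96 in wild-type Salmonella libraries and at 2.64, 1.96 and 2.70 in knockout ones (F-1, M-1, M-2).

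Of the neutrophil markers, 17 of 22 tested members were lower (21 were lower adjusted over the list alone, and 11 passed in voom), median -2.53. The neutrophil list had adjusted p = 2.11e-14, and adjusted p = 0.374 with an estimated correlation. Retnlg was among them (-3.59, adjusted p = 0.0119). Of the chemokines, 7 of 15 tested members were lower (1 was higher and 10 were lower adjusted over the list alone, and 4 passed in voom), median -1.78. The chemokine list had adjusted p = 8.05e-06, and adjusted p = 0.374 with an estimated correlation. Of the inflammatory cytokines, 0 of 18 tested members passed in limma and 0 in voom, with 8 at an unadjusted p under 0.05 (7 were lower adjusted over the list alone), median -0.38 (-0.22 with FPKM as deposited). The cytokine list had adjusted p = 0.0181, and adjusted p = 0.643 with an estimated correlation. The cytokine call ended without wild-type Salmonella F-1 (adjusted p = 0.191). Of the NF-kB target and feedback genes, 7 of 24 tested members were lower (16 were lower adjusted over the list alone), median -0.91. The NF-kB list had adjusted p = 2.35e-07, and adjusted p = 0.439 with an estimated correlation. Sod2 was lower (-1.53, adjusted p = 0.017). Of the acute-phase, complement and antimicrobial genes, 10 of 20 tested members were lower (16 were lower adjusted over the list alone, and 6 passed in voom), median -1.62. The acute-phase list had adjusted p = 3.9e-10, and adjusted p = 0.374 with an estimated correlation. Lcn2 was lower (-3.69, adjusted p = 0.0224). Of the inflammasome and pyroptosis genes, 4 of 17 tested members were lower (1 was higher and 8 were lower adjusted over the list alone, and 2 passed in voom), median -0.34 (-0.17 with FPKM as deposited). The inflammasome list had adjusted p = 0.00855, and adjusted p = 0.517 with an estimated correlation. Of the immediate early and stress genes, 3 of 18 tested members were lower (2 were higher and 8 were lower adjusted over the list alone), median -0.48 (-0.30 with FPKM as deposited). The immediate early list had adjusted p = 0.00951, and adjusted p = 0.679 with an estimated correlation. The immediate early call ended without knockout Salmonella M-1 (adjusted p = 0.057).

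Of the endothelial cell markers, 15 of 20 tested members were lower (16 were lower adjusted over the list alone), median -0.91. The endothelial list had adjusted p = 3.9e-10, and adjusted p = 0.374 with an estimated correlation. Sox18 was lower (-1.36, adjusted p = 0.00669). Of the erythroid and platelet markers, 7 of 8 tested members were lower (7 were lower adjusted over the list alone, and 3 passed in voom), median -2.56. The erythroid and platelet list had adjusted p = 1.92e-07, and adjusted p = 0.374 with an estimated correlation. Pf4 was at 31.2 ± 6.58 against 132 ± 10.1 FPKM (log2 fold change -2.25, SE 0.16, adjusted p = 0.000123). Of the coagulation and fibrinolysis genes, 9 of 15 tested members were lower (13 were lower adjusted over the list alone, and 4 passed in voom), median -1.23. The coagulation list had adjusted p = 3.34e-07, and adjusted p = 0.374 with an estimated correlation. Of the fibroblast and pericyte markers, 6 of 21 tested members were lower (10 were lower adjusted over the list alone, and 3 passed in voom), median -0.70. The fibroblast list had adjusted p = 0.000334, and adjusted p = 0.374 with an estimated correlation. Of the tumour epithelial markers, 1 of 4 tested members was lower (3 were lower adjusted over the list alone), median -0.79. The epithelial list had adjusted p = 0.022, and adjusted p = 0.374 with an estimated correlation. Of the skeletal muscle markers, 2 of 12 tested members were lower (3 were lower adjusted over the list alone, and 0 passed in voom), median -1.54. The muscle list had adjusted p = 0.00163, and adjusted p = 0.517 with an estimated correlation. Knockout Salmonella F-1 was at 2.59 for the muscle list, like the wild-type Salmonella libraries (2.82, 2.66 and 1.78), and M-1 and M-2 were at -0.14 and 0.67. Of the oxidative phosphorylation genes, 0 of 25 tested members passed in limma and 0 in voom, with 9 at an unadjusted p under 0.05 (0 adjusted over the list alone), median -0.26 (-0.084 with FPKM as deposited). The oxidative phosphorylation list had adjusted p = 0.00163, and adjusted p = 0.679 with an estimated correlation. Of the type I interferon-stimulated genes, 16 of 34 tested members were higher (19 were higher and 2 were lower adjusted over the list alone), median 0.63. The type I interferon list had adjusted p = 1.33e-09, and adjusted p = 0.374 with an estimated correlation. Ifit3b was higher in knockout hosts (1.37, adjusted p = 0.0149), though it shares fragments with its near-identical neighbour Ifit3, and Ifi44 was too (1.13, adjusted p = 0.0154). The other 14 lists did not pass, and with FPKM as deposited the medians of the MHC class I, cytotoxic, macrophage and keratinocyte lists changed sign.

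Wild-type Salmonella M-2 stood apart from its mates: scaling factors were 0.844 and 0.845 for F-1 and M-1 and 1.032 for M-2. Limma called 1063 genes between the host genotypes under Salmonella, 355 higher and 708 lower in knockout hosts (33.4% higher), with 3687 at an unadjusted p under 0.05. With FPKM as deposited, where the median of all genes shifted by 0.161, 58.5% of the calls were higher. At least 1 on the log2 scale was reached by 411 (21 higher, 390 lower). Of the calls, 1049 had no overlap between groups, which choosing genes by p favours. Of all genes 25.7% had none, against 10% expected by chance. The count was 41 without wild-type Salmonella F-1, 105 without M-1 and 4649 without M-2, and 579, 36 and 53 without knockout Salmonella F-1, M-1 and M-2; voom called 531 (178 higher, 353 lower) and a fit of these groups alone 12. Of the 53 genes named by rule that passed, 47 lost the call without at least 1 library (44, 38, 0, 16, 46 and 43 in the same order); Ifit1bl1, Ngp, Saa1, Tmem40, Pf4 and Sox18 were the other 6. Of the 53, 39 passed in voom.

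The interaction asked whether the treatment effect differed between host genotypes, and it called 3 genes, each with the smaller or opposite effect in knockout hosts. Pf4 (chromosome 5, 90772435 to 90773383) rose in both, by 3.93 in wild-type and 1.78 in knockout hosts (difference -2.15, adjusted p = 0.00848). Tmem40 (chromosome 6, 115729131 to 115762410) was at 1.21 ± 0.325 and 4.21 ± 0.603 FPKM in wild-type hosts and at 2.41 ± 0.64 and 1.25 ± 0.207 in knockout hosts (difference -2.33, adjusted p = 0.00848). Fabp7 (chromosome 10, 57784881 to 57788450), a fatty acid binding protein gene named after its values were seen, was at 4.18 ± 1.36 FPKM in wild-type Salmonella tumours and at 0.106 ± 0.093, 0.148 ± 0.129 and 0.257 ± 0.136 in the wild-type PBS, knockout PBS and knockout Salmonella groups (difference -2.84, adjusted p = 0.0275). The call on Fabp7 ended without wild-type PBS F-1 (adjusted p = 0.0954), wild-type PBS M-1 (adjusted p = 0.0977), wild-type PBS M-2 (adjusted p = 0.0821), knockout PBS F-1 (adjusted p = 0.119), knockout PBS M-1 (adjusted p = 0.129), knockout Salmonella F-1 (adjusted p = 0.0588), knockout Salmonella M-1 (adjusted p = 0.0642) and knockout Salmonella M-2 (adjusted p = 0.0828).

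Among the lists the interaction was lower in knockout hosts for neutrophil markers, where 0 of 22 tested members passed in limma and 0 in voom, with 19 at an unadjusted p under 0.05 (19 were lower adjusted over the list alone), median -2.35. The neutrophil list had adjusted p = 1.55e-14, and adjusted p = 0.456 with an estimated correlation. Of the chemokines, 0 of 15 tested members passed in limma and 0 in voom, with 6 at an unadjusted p under 0.05 (6 were lower adjusted over the list alone), median -1.71. The chemokine list had adjusted p = 7.94e-06, and adjusted p = 0.456 with an estimated correlation. Of the NF-kB target and feedback genes, 0 of 24 tested members passed in limma and 0 in voom, with 11 at an unadjusted p under 0.05 (2 were lower adjusted over the list alone), median -0.85. The NF-kB list had adjusted p = 8.32e-09, and adjusted p = 0.53 with an estimated correlation. Of the acute-phase, complement and antimicrobial genes, 0 of 20 tested members passed in limma and 0 in voom, with 13 at an unadjusted p under 0.05 (10 were lower adjusted over the list alone), median -1.79. The acute-phase list had adjusted p = 6.35e-10, and adjusted p = 0.456 with an estimated correlation. Saa1 differed by -4.34, adjusted p = 0.0851. Of the endothelial cell markers, 0 of 20 tested members passed in limma and 0 in voom, with 15 at an unadjusted p under 0.05 (14 were lower adjusted over the list alone), median -0.82. The endothelial list had adjusted p = 1.97e-09, and adjusted p = 0.456 with an estimated correlation. Of the erythroid and platelet markers, 1 of 8 tested members was lower (2 were lower adjusted over the list alone, and 0 passed in voom), median -1.56. The erythroid and platelet list had adjusted p = 1.94e-05, and adjusted p = 0.456 with an estimated correlation. Of the coagulation and fibrinolysis genes, 0 of 15 tested members passed in limma and 0 in voom, with 10 at an unadjusted p under 0.05 (4 were lower adjusted over the list alone), median -1.10. The coagulation list had adjusted p = 6.3e-06, and adjusted p = 0.53 with an estimated correlation. Of the skeletal muscle markers, 0 of 12 tested members passed in limma and 0 in voom, with 2 at an unadjusted p under 0.05 (2 were lower adjusted over the list alone), median -1.56. The muscle list had adjusted p = 0.00167, and adjusted p = 0.565 with an estimated correlation. Of the oxidative phosphorylation genes, 0 of 25 tested members passed in limma and 0 in voom, with 2 at an unadjusted p under 0.05 (0 adjusted over the list alone), median -0.30 (-0.12 with FPKM as deposited). The oxidative phosphorylation list had adjusted p = 0.000632, and adjusted p = 0.643 with an estimated correlation.

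Of the inflammatory cytokines, 0 of 18 tested members passed in limma and 0 in voom, with 5 at an unadjusted p under 0.05 (0 adjusted over the list alone), median -0.33 (-0.16 with FPKM as deposited). The cytokine list had adjusted p = 0.0342, and adjusted p = 0.643 with an estimated correlation. The cytokine call ended in voom and without wild-type PBS F-1 (adjusted p = 0.0696), wild-type Salmonella F-1 (adjusted p = 0.328), knockout PBS F-1 (adjusted p = 0.0727), knockout PBS M-1 (adjusted p = 0.11) and knockout Salmonella M-1 (adjusted p = 0.097). Of the MHC class I presentation genes, 0 of 21 tested members passed in limma and 0 in voom, with 0 at an unadjusted p under 0.05 (0 adjusted over the list alone), median -0.24 (-0.057 with FPKM as deposited). The MHC class I list had adjusted p = 0.0342, and adjusted p = 0.796 with an estimated correlation. The class I call ended without wild-type PBS M-2 (adjusted p = 0.0962), wild-type Salmonella F-1 (adjusted p = 0.274), wild-type Salmonella M-1 (adjusted p = 0.0996), knockout PBS F-1 (adjusted p = 0.125), knockout PBS M-1 (adjusted p = 0.381) and knockout Salmonella M-1 (adjusted p = 0.0875). Of the fibroblast and pericyte markers, 0 of 21 tested members passed in limma and 0 in voom, with 4 at an unadjusted p under 0.05 (0 adjusted over the list alone), median -0.52 (-0.34 with FPKM as deposited). The fibroblast list had adjusted p = 0.0149, and adjusted p = 0.605 with an estimated correlation. The fibroblast call ended without wild-type PBS M-1 (adjusted p = 0.084), knockout PBS F-1 (adjusted p = 0.107) and knockout Salmonella M-1 (adjusted p = 0.146). Of the inflammasome and pyroptosis genes, 0 of 17 tested members passed in limma and 0 in voom, with 5 at an unadjusted p under 0.05 (1 was lower adjusted over the list alone), median -0.39 (-0.21 with FPKM as deposited). The inflammasome list had adjusted p = 0.00738, and adjusted p = 0.565 with an estimated correlation. The inflammasome call ended without knockout PBS M-1 (adjusted p = 0.085). Of the type I interferon-stimulated genes, whose interaction was higher, 0 of 34 tested members passed in limma and 0 in voom, with 13 at an unadjusted p under 0.05 (1 was higher adjusted over the list alone), median 0.37. The type I interferon list had adjusted p = 7.94e-06, and adjusted p = 0.565 with an estimated correlation. Of the hypoxia and glycolysis genes, also higher, 0 of 25 tested members passed in limma and 0 in voom, with 5 at an unadjusted p under 0.05 (0 adjusted over the list alone), median 0.20 (0.39 with FPKM as deposited). The hypoxia list had adjusted p = 0.00233, and adjusted p = 0.607 with an estimated correlation. The hypoxia call ended without wild-type Salmonella M-2 (adjusted p = 0.221) and knockout Salmonella F-1 (adjusted p = 0.0503). The other 14 lists did not pass; with FPKM as deposited the medians of the interferon-gamma, macrophage, cell cycle and angiogenesis lists changed sign.

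For the interaction 1746 genes had an unadjusted p under 0.05, and voom called 0 genes, with adjusted p = 0.0508 for Pf4 and Tmem40 and 0.403 for Fabp7. Over 21 alternatives the adjusted p ranged from 0.00157 to 0.0508 for Pf4, from 0.00166 to 0.0508 for Tmem40 and from 0.00106 to 0.403 for Fabp7. The count was 5 without wild-type Salmonella F-1, 9 without M-1 and 2303 without M-2.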

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

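Of the tests here, the splits of the libraries, the length and GC checks, the thinning and the left-out libraries were set before their values were seen; the 2 tests of a mislabelled library, the first with a bound that replaced a narrower one that would have argued against it, and the test against other cell lists were chosen only after the result was seen, and the length and GC trend removal was an alternative added after seeing the data.

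The results singled out are those whose treatment effect differed between host genotypes in the test of the difference. They were Pf4 (-2.15), Tmem40 (-2.33) and Fabp7 (-2.84) on the log2 scale. The list medians of the difference, knockout minus wild type, were -2.35 for neutrophil markers, -1.71 for chemokines, -0.33 for inflammatory cytokines, -0.85 for NF-kB targets, 0.37 for type I interferon-stimulated genes, -0.24 for MHC class I, -0.82 for endothelial, -0.52 for fibroblast, -1.56 for skeletal muscle and -1.56 for erythroid and platelet markers. They were 0.20 for hypoxia and glycolysis, -0.30 for oxidative phosphorylation, -1.79 for acute-phase, -1.10 for coagulation and -0.39 for inflammasome genes, and none passed with an estimated correlation.

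The 3 libraries against 3 of a comparison make 10 splits, the real one included, too few for a share under 0.05. Salmonella in wild-type hosts gave 4312 genes, reached in 1 of 10 splits, the real one, with 0 in the highest other split. In knockout hosts it gave 92, also reached in 1 of 10, the real one, with 0 in the highest other. Those other splits mix PBS and Salmonella libraries within an arm, which widens the spread. Their 0 therefore does not show what chance gives. Knockout against wild type gave 0 genes under PBS, as many as in 10 of 10 splits, with 0 in the highest other, and 1063 under Salmonella, as many as in 1 of 10, with 486 in the highest other. For the interaction, 12 of 100 splits by genotype within treatment gave at least 3 genes, with 237 in the highest other. All 12 kept both Salmonella groups intact, so they still held the genotype contrast under Salmonella and do not show what chance gives. The other splits put the difference between the Salmonella groups inside each arm, which widens the spread, so they do not show it either, and whether chance can be excluded stays open. The cause of the large counts in some splits was not tested.

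Most genes called for the mean treatment effect had the smaller effect in knockout hosts (85%). Removing length and GC trends left 81.5%, thinning every library to the depth of the shallowest library left 85.1%, and the lowest share without 1 library was 76.8% (without knockout PBS M-2), all of which argue against bias of length and GC, depth or 1 library alone as the cause. Leaving out 1 library does not test 2 together. Wild-type Salmonella F-1 and M-1 had scaling factors of 0.844 and 0.845, against 1.032 for M-2. Choosing genes by the mean effect can also favour the genotype with the wider spread. Under Salmonella that was wild type, with chi-square per gene between mates of 62.7 to 196 against 22.2 to 47.2. Under PBS it was knockout (35.1 to 74.2 against 19 to 37). Within these limits a weaker response to Salmonella in hosts without TLR4 may be a candidate explanation, as a hypothesis found on the same data. A smaller share of neutrophils, whose markers moved in the same direction, stays open, while the macrophage, T and NK cell, dendritic and B cell lists did not pass for the interaction (medians -0.12, -0.41, -0.33 and 0.32), although with FPKM as deposited the macrophage (0.06) and the T and NK cell (-0.33) lists did; bacterial load was not analysed here.

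Wild-type Salmonella M-2 lay between its group and the knockout group, at 22.8 on the first principal component (68.3% of the variance), against 63.2 and 69.3 for F-1 and M-1 and 13.5, -6.8 and 2.9 for the knockout libraries. On a scale of 1000 genes from knockout (0) to the other wild-type libraries (1) it lay at 0.345, above the highest knockout library (0.203) by less than their SD (0.205), and at 0.359 with length and GC trends removed, which argues against such a bias in the other wild-type libraries. Of 17 lists that differed between the Salmonella groups without it, 7 placed it beyond every knockout library on the wild-type side by more than their SD, neutrophil markers (mean log2 level against wild-type PBS 3.96, against at most 2.70), erythroid and platelet markers (1.74 against at most 0.43) and type I interferon-stimulated genes (-0.06 against at least 0.60) among them; its Pf4 level, at 142 against at most 38.7 FPKM, was above theirs too. These values speak against a mislabelled knockout library, but 8 of the 17 lists did not place it beyond every knockout library on the wild-type side. For cytokines it lay within their range (0.835, against 0.515 to 0.956). For MHC class I it lay below all of them (-0.407, against -0.195 to -0.085), so that list does not speak for a knockout label. With 3 knockout libraries a wrong label of this library stays open. It may also be a host with a weaker response; the count of interaction genes was 2303 without it, against 3.

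Limma called 16 of 34 type I interferon-stimulated genes higher in knockout than in wild-type hosts under Salmonella, and 12 passed in voom. With an estimated correlation the list did not pass in camera. The median difference of the list was 0.63. Removing length and GC trends left 0.624, which argues against that bias. If other cells held a lower share of the RNA in wild-type hosts, lists of other cells or processes should all be higher alike, but of 4 (macrophage, T and NK cell, MHC class I, cell cycle) the highest median was 0.102, for the cell cycle, and endothelial markers were lower (-0.91). Scaling shifts all lists alike and left this gap, since with FPKM as deposited the type I list was at 0.80 and the cell cycle list at 0.28. Medians were also positive for sterol genes (0.42, 2 of 26 called) and B cell markers (0.51, 1 of 4 called, the list not passed), so more B cell RNA was not excluded. None of the 4 lists holds markers of tumour cells, so a lower share of tumour-cell RNA in wild-type hosts was not excluded either. Y-linked genes go with it, at a mean of 33.7 CPM in wild-type and 15.1 in knockout Salmonella libraries of letter M. The tumour epithelial list (-0.79, 4 tested members) goes the other way. A stronger or longer interferon response in hosts without TLR4 may be a candidate explanation, as a hypothesis; a change within single cell types was not tested.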

How the results depend on the processing

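The pseudocounts, FPKM as deposited, voom, the length and GC correction and the minimum change were tests chosen only after seeing the data; the other settings were fixed beforehand. DESeq2, listed as an alternative for counts, was not run, since the deposited values were FPKM. The recovered fragments would have allowed it, and voom was the only count-based test run on them.

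For Salmonella in wild-type hosts (4312 genes) a fit of only the groups compared gave 2420 and a minimum change of 1 gave 876. For knockout hosts (92; 52 higher, 40 lower) no filter gave 46, voom 22 (6 higher, 16 lower), only the groups compared 186 and the minimum change 28. For knockout against wild type under PBS, where limma called 0, with 176 at an unadjusted p under 0.05 and 0 by voom, no filter gave 1. Under Salmonella (1063) voom gave 531, only the groups compared 12 and the minimum change 411. For the interaction (3) FPKM as deposited gave 6, voom 0 and the length and GC correction 5. The minimum change removes genes by construction. A fit of fewer samples has fewer degrees of freedom, but in knockout hosts it gave more genes (186 against 92). The fit of all 12 libraries takes 1 spread per gene over all groups, so its p-values assume equal spread. The spread was unequal: chi-square per gene between mates was 62.7 to 196 for wild-type Salmonella and 19 to 37 for wild-type PBS. The 12 and 1063 genes under Salmonella therefore rest on different spreads. For the rest the cause was not tested.

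The replicate labels were also tried as a block. They do not pair the libraries: over 18 same-label pairs the correlation of deviations was -0.332 to 0.397 (median 0.05), above 0.1 in 7, against a median of -0.031 for other labels. With the block the counts were 4245 in wild-type and 46 in knockout hosts (23 higher, 23 lower), 0 under PBS, 1024 under Salmonella and 4 for the interaction.

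Leaving out 1 library gave 2157 to 6290 genes in wild-type hosts, 4 to 297 in knockout hosts, 36 to 4649 between genotypes under Salmonella and 2 to 2303 for the interaction, while under PBS it stayed at 0; the correlation of both treatment effects was 0.698 to 0.793. An arm of 2 libraries shares the spread of the others. Under PBS, between genotypes, the interferon-gamma list reversed to -0.18 (range to 0.69) and the cytotoxic list to -0.18 (range to 0.75) without knockout PBS M-1. The macrophage list reversed to 0.30 (range from -0.26) and the acute-phase list to 0.23 (range from -0.20) without knockout PBS M-2; the cause was not tested. With 1 library left out, 3183 of 3600 results of named genes and 941 of 1044 of gene lists kept their direction and side of the threshold, 307 and 50 lost the call, and 110 and 49 gained one. Under the other alternatives 4706 of 4900 and 1264 of 1305 kept them, 148 and 13 lost the call, and 46 and 28 gained one. The lowest depth, 30512075 fragments, limits 1 kb genes below 0.0983 FPKM.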

Other observations

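The gene lists in this part and the test of Y-linked genes were chosen only after the result was seen; 5 such lists were tested in 5 comparisons, 25 tests in all.

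In camera, adjusted over the 25 tests, 17 passed with the preset correlation of 0.01, and 0 with an estimated correlation, where 1 had an unadjusted p under 0.05. Those that passed were mast cell markers in wild-type hosts, between genotypes under Salmonella and for the interaction; sterol genes in all comparisons except that under PBS; glucocorticoid-induced genes in all 5; chaperones in each host genotype and under PBS; and collagen genes under Salmonella and for the interaction.

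Of the mast cell markers, 8 of 10 tested members rose in wild-type hosts, with a median of 2.49; Hdc is also a neutrophil list gene. In knockout hosts limma called 0 of 10 (median 0.071), and between genotypes under Salmonella 5 were lower in knockout hosts (median -2.06), against 1 call in voom. Of the genes of sterol and fatty acid synthesis, 15 of 26 fell in wild-type hosts, with a median of -0.53, against 0 of 26 in knockout hosts (median -0.12) and 2 higher in knockout hosts under Salmonella (median 0.42), against 1 call in voom. Of the glucocorticoid-induced genes, which share Dusp1, Angptl4, Ddit4, Zfp36 and Il1r2 with the lists fixed beforehand, 9 of 18 rose and 1 fell in wild-type hosts (median 0.67), and 0 passed in knockout hosts (median 0.38); under Salmonella 9 were lower in knockout hosts (median -0.76). Cytosolic chaperone genes, of which Hspa1a, Hspa1b, Hsph1 and Dnajb1 are on the stress list, had 7 of 21 members higher in wild-type hosts (median 0.28, or 0.08 with FPKM as deposited) and 2 of 21 in knockout hosts (median 0.31), where voom called 1; under Salmonella 2 were lower in knockout hosts, with a median of -0.046 that was 0.13 with FPKM as deposited. Fibrillar collagen and matrix-modifying genes, which share Col1a1, Col1a2, Col3a1, Col5a1, Loxl1 and P4ha1 with earlier lists, went both ways in wild-type hosts, with 10 of 24 higher and 6 lower (median 0.41), and limma called 0 in knockout hosts (median -0.23); under Salmonella 9 were lower in knockout hosts (median -0.605). At an unadjusted p under 0.05 and by voom the lists of 0 calls in knockout hosts held 2 and 0 mast cell markers, 1 and 0 sterol and fatty acid synthesis genes, 7 and 0 glucocorticoid-induced genes and 11 and 0 fibrillar collagen and matrix-modifying genes. Under PBS and for the interaction limma and voom called 0 members of each list, with at most 1 and 9 members at an unadjusted p under 0.05.

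Y-linked genes were near 0 in the libraries with title letter F, at 0 to 0.03 CPM of recovered fragments, and present in those with letter M. Wild-type M libraries held 19.9 and 16.0 CPM under PBS and 40.9 and 26.5 under Salmonella; knockout M libraries held 19.4 and 7.3 under PBS and 13.8 and 16.4 under Salmonella. All 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) were higher in both wild-type Salmonella M libraries than in both PBS ones, which a larger share of host RNA after Salmonella may explain, as a hypothesis from 2 libraries against 2. A change of these genes within cells was not tested.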
